A study of Homo sapiens with 12 samples.

How the data were processed

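Total RNA of MIA PaCa-2 cells, an established human pancreatic cancer line, was sequenced in 12 libraries that fall into 4 groups of 3. The groups combine L-glutamine at 2 or 40 mM with gemcitabine at 0 or 0.5 µM for 48 h. Per the labels, cells were grown in glutamine-free medium to which glutamine was added back, RNA was extracted with a column kit, and a sequencing company made the libraries. The series design describes the 3 samples of a group as biological replicates. The genome build, aligner, counting program and its strand setting are not given in the sources used here, so no coordinates are printed.

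The deposited table holds log2 values for 15090 gene symbols, and per the file headers its columns carry the library names that the sample titles give. Its unit was worked out from the values. Each deposited log2 value equals the log2 of a value in reads per 1000000 (RPM) plus a pseudocount of 1, and in every library the RPM values of 100% of genes were whole multiples of what 1 read is worth, within a tolerance of 0.05 read. Whole reads could therefore be recovered, and they add up to between 21723094 and 32811746 per library over the listed genes. The library sums of RPM values have a geometric mean of 1000000, which is the pattern left by scaling factors between libraries; these factors ranged from 0.9794 to 1.0292, with 1.0263 to 1.0292 in the 3 libraries at 40 mM with drug and at most 1.002 in the other 9, and the method behind them is not given in the sources used here. Each listed gene has at least 10 reads in at least 2 libraries. Of the symbols, 14299 are current gene names, 248 are older names and 543 matched neither; 2 symbols look like dates, as spreadsheet programs write some gene names. Symbols are printed as the table gives them.

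A gene was tested where at least 3 of the 12 libraries reached 1 RPM, which kept 12789 genes and left 2301 untested. Tested genes had a median of 721 reads per library, where counting error alone gives a coefficient of variation of 3.7%. The deposited log2 values were fitted with limma (version 3.58.1, R 4.3.3) as 4 group means over all 12 libraries, with empirical Bayes moderation and a mean-variance trend. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. All fold changes are on the log2(value + 1) scale, which understates the change of genes at low level. The comparisons were 40 against 2 mM glutamine without and with the drug, the drug against none at each glutamine level, and the interaction, which is the drug response at 40 mM minus that at 2 mM. The plan made before the table was read foresaw count models where whole reads could be recovered. They were left out by a choice that rested on the deposited log scale, although whole reads were recovered. Limma with voom weights on the recovered reads took their place.

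Gene lists were tested as groups. Of 35 lists fixed before the data were examined, 32 had at least 5 tested members and entered camera with a preset inter-gene correlation of 0.01, adjusted over 160 tests (32 lists in 5 comparisons). In all, 83 of these tests passed the threshold, and 26 of them also passed with a correlation estimated from the residuals. Named genes follow a rule fixed in advance: in each pairwise comparison the 8 largest rises and 8 largest falls among genes with a symbol, protein-coding where known, past the threshold, with all 3 libraries of one group above all 3 of the other and a mean level at or above the median of tested genes; up to 4 members, by smallest p, of each list that passed camera or had at least 5 members past the threshold and of some lists whatever their result; a fixed set of transport, drug metabolism and stress genes; and the 12 smallest adjusted p of the interaction at that level. Results of 4 genes that this rule names are not reported here, though they remain in all fits and counts. Genes with near-identical relatives, such as histone, ribosomal protein, IFITM and AKR1C genes, are uncertain, because the counting could have split or merged their reads.

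Replicates were compared before averaging. Within groups, the chi-square of recovered reads over its degrees of freedom lay between 2.42 and 5.87 for every pair, so no pair matched within sampling noise and each library counts once. The procedure was tested on simulated reads drawn from the real means and library sizes, with a dispersion of 0.000999. That estimate was changed after the outcome of the simulation had been seen: reads were scaled for depth, and the median was taken over gene means. The first estimate, 0.00802, had recovered 17.9% of 1.2-fold changes for glutamine without drug and 1.5% for the interaction. The median SE for glutamine without drug is 0.069 in the real data, against 0.111 with the first estimate and 0.057 with the changed one, so the simulated spread is below the real one and the shares given next run high. The fits of the real data were not changed. Among 12789 genes with 200 changed, limma recovered 67.2% of 1.2-fold, 89.6% of 1.5-fold and 98.5% of 2-fold changes for glutamine without drug. For the interaction, the recovered shares were 38.8%, 77.6% and 97%. Of the 12589 unchanged genes, 0.079% and 0.048% were called in those simulations. Alternatives covered the pseudocount, the filter on low values, the scaling, the libraries in the fit, a block on the replicate number, library weights, robust moderation, each library left out in turn, and the list tests fry and camera with an estimated correlation. Voom on recovered reads, a test against a fold of 1.1, and removal of the trend with level, GC content and transcript length were added after the data were seen. Figures and tables were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.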

Results

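The transcriptome of MIA PaCa-2 cells was measured in 4 groups of 3 libraries after 48 h in 2 or 40 mM L-glutamine, without or with 0.5 µM gemcitabine, a deoxycytidine analogue that stops DNA synthesis. The series title asks how a high glutamine dose affects amino acid transport and the sensitivity of pancreatic cancer cells to chemotherapy. Reads in listed genes ranged from 21723094 to 32811746 per library. On the first principal component, which held 40.1% of the variance over tested genes, all 6 drug-treated libraries lay apart from the 6 untreated ones. The second held 18.8% and parted the glutamine levels.

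Glutamine at 40 mM without the drug raised genes of DNA replication and some genes of the unfolded protein response and lowered epithelial, heat shock and growth factor response genes. Most changes were small: the median size of a called change was 0.21 on the log2 scale. Among called genes at or above the median level, with all 3 libraries of one group above all 3 of the other, the largest rises were PFKFB4, a regulator of glycolysis (log2 fold change 0.58 ± 0.091, SE, n = 3 per group), TSPYL2 (0.56 ± 0.047) and CDC6, which loads the replicative helicase (0.52 ± 0.048). VGF, FAM111B, CHPF, H2AX and ZBTB1 followed, at 0.44 to 0.51. By the same rule, the largest falls were DHRS2, a short-chain dehydrogenase (−0.90 ± 0.06), the adhesion molecule L1CAM (−0.74 ± 0.061) and the tight junction gene CLDN4 (−0.73 ± 0.048). ETV4, CCN1, IFITM1, PLAUR and PLEKHG2 fell by 0.61, 0.58, 0.57, 0.52 and 0.49. DHRS2 went from 61.1 ± 0.786 to 32.4 ± 2.27 reads per 1000000 (RPM; SD, n = 3).

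Of 60 tested genes of G1/S and DNA replication, 34 rose and 0 fell with glutamine alone (39 and 0 adjusted over the list alone, camera adjusted p = 2.3e-15, and adjusted p = 0.0423 with an estimated correlation). MCM4, a helicase subunit, rose by 0.20 ± 0.029, DTL by 0.30 ± 0.045 and RRM2, a subunit of ribonucleotide reductase, by 0.24 ± 0.031. Among 23 genes of the unfolded protein response, 9 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 9.07e-08, and adjusted p = 0.0371 with an estimated correlation). The chaperones HSPA5 and CALR rose by 0.30 ± 0.026 and 0.31 ± 0.027. In the heat shock list 1 gene rose and 10 of 20 fell (1 and 10 adjusted over the list alone, camera adjusted p = 5.14e-06, and adjusted p = 0.0367 with an estimated correlation), with HSP90AA1 at −0.30 ± 0.026 and HSPD1 at −0.29 ± 0.027.

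Of 32 immediate-early and MAPK feedback genes, 2 rose and 12 fell (2 and 16 adjusted over the list alone, camera adjusted p = 4.16e-05, and adjusted p = 0.0224 with an estimated correlation), among them FOSL1 (−0.26 ± 0.039) and JUNB (−0.41 ± 0.066). Of 14 epithelial genes, 0 rose and 5 fell (1 and 6 adjusted over the list alone, camera adjusted p = 5.52e-05, and adjusted p = 0.032 with an estimated correlation), including the keratins KRT8 (−0.30 ± 0.026) and KRT18 (−0.42 ± 0.035). Of 19 senescence-linked surface and secreted genes, 1 rose and 11 fell (1 and 13 adjusted over the list alone, camera adjusted p = 1.43e-08, and adjusted p = 0.0371 with an estimated correlation), with AXL at −0.34 ± 0.033. In the glycolysis list 10 of 25 rose and 1 fell (10 and 2 adjusted over the list alone, camera adjusted p = 1.62e-05, but adjusted p = 0.299 with an estimated correlation): the glucose transporter SLC2A1 rose by 0.37 ± 0.041 and PDK1 by 0.38 ± 0.06, while SLC2A3 fell by 0.66 ± 0.093. Of 56 genes of G2/M and mitosis, 4 rose and 18 fell (4 and 18 adjusted over the list alone, camera adjusted p = 0.00154, but adjusted p = 0.375 with an estimated correlation), such as CDC20 (−0.25 ± 0.033).

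Amino acid transport, named in the series title, showed no common direction. Of 25 tested transporters, 4 rose, 3 fell and 18 did not pass at 40 mM without the drug (6 and 3 adjusted over the list alone, camera adjusted p = 0.954). The median of the list was −0.035 and its mean 0.003. SLC7A5, a transporter of large neutral amino acids, fell by 0.25 ± 0.032, from 476 ± 27 to 401 ± 5.58 RPM (SD, n = 3), and SLC1A5, a glutamine importer, fell by 0.13 ± 0.032. SLC1A4 rose by 0.42 ± 0.105. SLC38A1 (−0.01 ± 0.034) and SLC38A2 (0.02 ± 0.027) did not pass. In the glutamine metabolism list 3 of 27 rose and 3 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.318), and GFPT2 of hexosamine synthesis fell by 0.47 ± 0.068. TXNIP fell by 0.35 ± 0.046. The call of SLC1A5 ended when the trend with level, GC content and transcript length was removed (−0.09, limma adjusted p = 0.0523).

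In total, 1076 genes were higher and 1166 lower at 40 mM glutamine without the drug, which is 17.5% of the 12789 tested (limma). Only 1 of them rose and 2 fell by 2-fold or more. The groups did not overlap for 31.1% of genes, where chance gives 10%. CDKN1A, an inhibitor of the cell cycle, had −0.49 ± 0.145, but its call ended without replicate 1 at 2 mM (adjusted p = 0.0896) and without replicate 2 at 40 mM (adjusted p = 0.203). GDF15 had −0.64 ± 0.155 near the level needed for testing, with 2.92 ± 0.634 RPM at 2 mM and 1.49 ± 0.207 RPM at 40 mM (SD, n = 3).

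**Figure D1:**
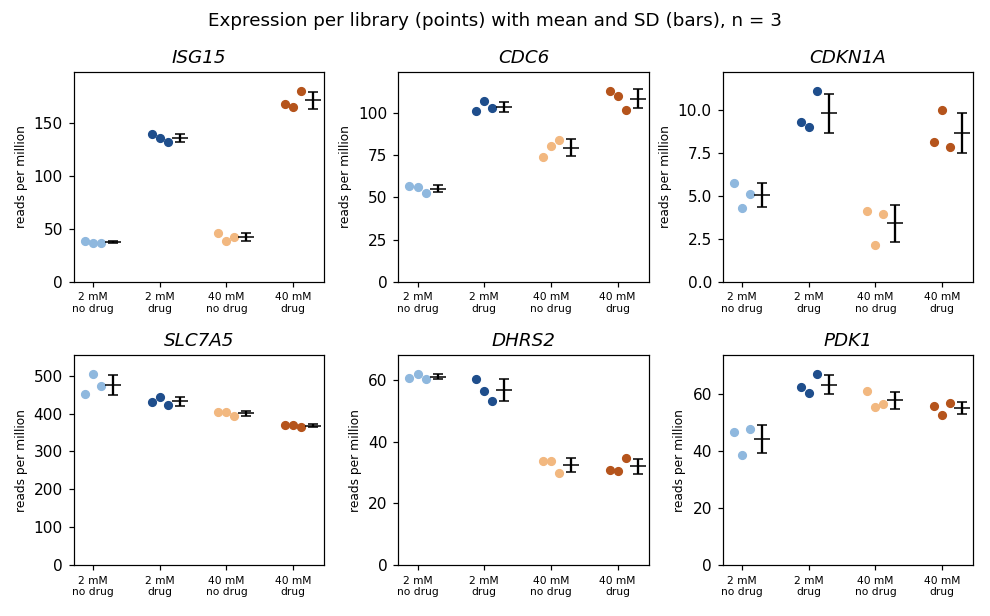
Reads per 1000000 (RPM) in each of the 12 libraries (points) for 6 genes, with the group mean and SD beside them (bars, n = 3); the x axis gives glutamine and drug. ISG15 averaged 37.3 and 42.1 without the drug against 135 and 171 with it, and DHRS2 averaged 61.1 and 56.9 at 2 mM against 32.4 and 32.1 at 40 mM.

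Gemcitabine at 2 mM glutamine raised interferon-stimulated genes and genes of DNA replication, the lists with the highest medians there. By the rule of level and separation given above, the largest rises began with OASL. OASL rose by 1.95 ± 0.053, ISG15, a ubiquitin-like antiviral protein, by 1.83 ± 0.05, IFIT3 by 1.57 ± 0.042, and the helicase genes DDX60 and DDX58 by 1.45 ± 0.082 and 1.44 ± 0.054. ISG15 went from 37.3 ± 1.15 to 135 ± 3.56 RPM (SD, n = 3). EGR1, IFIT2 and CD68 completed these rises at 1.17, 1.11 and 1.09. The largest falls by that rule were KANK4 (−0.84 ± 0.054), the stress gene DDIT4 (−0.78 ± 0.055) and AKR1C1, an aldo-keto reductase (−0.73 ± 0.041), followed by PLPPR3, KLHL24, DBP, CLIP2 and MACROD1 at −0.72 to −0.68.

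Of 38 interferon-stimulated genes, 32 rose and 4 fell with the drug at 2 mM (32 and 4 adjusted over the list alone, list median 0.699, camera adjusted p = 1.69e-24, and adjusted p = 0.00739 with an estimated correlation). In the G1/S and DNA replication list 59 of 60 rose and 0 fell (59 and 0 adjusted over the list alone, list median 0.449, camera adjusted p = 1.07e-47, and adjusted p = 0.00739 with an estimated correlation), including CDC6 (0.90 ± 0.048), the sliding clamp PCNA (0.67 ± 0.036) and MCM4 (0.62 ± 0.029). Of 56 mitosis genes, 47 rose and 1 fell (48 and 2 adjusted over the list alone, camera adjusted p = 3.91e-22, and adjusted p = 0.0383 with an estimated correlation), with FOXM1 at 0.53 ± 0.033 and AURKB at 0.50 ± 0.04. Among 59 DNA damage genes 34 rose and 4 fell (36 and 5 adjusted over the list alone, camera adjusted p = 4.66e-11, but adjusted p = 0.0563 with an estimated correlation); the nuclease EXO1 rose by 0.84 ± 0.062 and CLSPN by 0.71 ± 0.047. Of 25 NRF2 and redox genes, 3 rose and 12 fell (3 and 13 adjusted over the list alone, camera adjusted p = 0.00108, and adjusted p = 0.0371 with an estimated correlation), such as the ferritin gene FTL (−0.55 ± 0.027) and NQO1 (−0.47 ± 0.027).

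Several genes of the nucleoside transport and gemcitabine metabolism list rose with the drug at 2 mM glutamine, while DCK and CDA did not pass. Of 25 tested genes of nucleoside transport and gemcitabine metabolism, 12 rose and 4 fell (12 and 5 adjusted over the list alone, camera adjusted p = 0.00462, but adjusted p = 0.106 with an estimated correlation). RRM2 rose by 0.76 ± 0.031, the thymidine kinase TK1 by 0.65 ± 0.042, RRM1 by 0.35 ± 0.032 and the nucleoside transporter SLC29A1 by 0.40 ± 0.041. RRM2, TK1 and RRM1 also belong to the G1/S and DNA replication list, of which 59 of 60 rose, so their rises are not separate evidence. DCK, which activates the drug, had 0.01 ± 0.082 and CDA, which inactivates it, had −0.24 ± 0.18, and neither passed. CDA averaged 2.2 and 1.76 RPM without and with the drug, near the level needed for testing, so a change in it could be missed. PMAIP1, a promoter of apoptosis, rose by 1.38 ± 0.088, CDKN1A by 0.84 ± 0.145 and ATF3 by 0.66 ± 0.116. ASNS, also at a low level, fell by 0.68 ± 0.147, from a mean of 3.66 to 1.92 RPM. Of 35 p53 target genes, 11 rose and 8 fell (14 and 8 adjusted over the list alone, camera adjusted p = 0.421).

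With the drug at 2 mM, 2237 genes were higher and 2185 lower, or 34.6% of those tested (limma), of which 35 rose and 1 fell by 2-fold or more. Groups did not overlap for 46.1% of genes, where chance gives 10%.

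At 40 mM glutamine the drug raised interferon-stimulated and cell cycle genes too. By the rule of level and separation, ISG15 rose by 2.00 ± 0.05, DDX60 by 1.91 ± 0.082, OASL by 1.89 ± 0.053, IFIT3 by 1.57 ± 0.042 and the transcription factor EGR1 by 1.51 ± 0.074, and DDX58, IFIT1 and OAS3 followed at 1.45, 1.28 and 1.25. UNC93B1, which guides Toll-like receptors, fell by 0.86 ± 0.044, MGAT5B by 0.81 ± 0.061 and ID2 by 0.74 ± 0.056, with DDIT4, DBP, PNPLA6, MACROD1 and SLC27A1 at −0.73 to −0.67. Of 38 interferon-stimulated genes, 33 rose and 1 fell (33 and 1 adjusted over the list alone, list median 0.953, camera adjusted p = 4.32e-36, and adjusted p = 0.00407 with an estimated correlation).

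Cell cycle lists rose at 40 mM as well. In the G1/S and DNA replication list 53 of 60 rose and 0 fell (55 and 0 adjusted over the list alone, list median 0.306, camera adjusted p = 4.51e-30, and adjusted p = 0.0183 with an estimated correlation), with RRM2 at 0.49 ± 0.031. Of 56 mitosis genes, 54 rose and 1 fell (55 and 1 adjusted over the list alone, list median 0.346, camera adjusted p = 1.41e-45, and adjusted p = 0.0183 with an estimated correlation), including HMMR (0.67 ± 0.039). Among 22 NF-kappaB and cytokine genes 12 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 2.09e-05, and adjusted p = 0.0365 with an estimated correlation): CSF3 rose by 1.22 ± 0.065 and CXCL8, a chemokine, by 0.90 ± 0.072. Fatty acid synthesis had 1 rise and 7 falls among 16 genes (1 and 7 adjusted over the list alone, camera adjusted p = 0.00177, and adjusted p = 0.0423 with an estimated correlation), with the desaturase SCD at −0.59 ± 0.03. Of 77 ribosomal protein genes, 0 rose and 65 fell (0 and 65 adjusted over the list alone, list median −0.163, camera adjusted p = 1.69e-24, but adjusted p = 0.153 with an estimated correlation). CDKN1A rose by 1.16 ± 0.145, GDF15 by 0.97 ± 0.155 and DCK by 0.36 ± 0.082. The interaction of CDKN1A, GDF15 and DCK did not pass, so a drug response that differs between glutamine levels is not shown for them. Without the drug at 40 mM, CDKN1A averaged 3.4 ± 1.09 and GDF15 1.49 ± 0.207 RPM (SD), near the level needed for testing.

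The drug response at 40 mM counted 1809 genes higher and 2070 lower, or 30.3% of those tested (limma), of which 45 rose and 0 fell by 2-fold or more. The drug responses at both glutamine levels share no libraries. Of the calls, 1211 were higher in both, where independent lists would share 316.4, and 1310 were lower in both, where independent lists would share 353.7. Among 2538 genes called in both, 17 went in opposite directions.

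**Figure D2:**
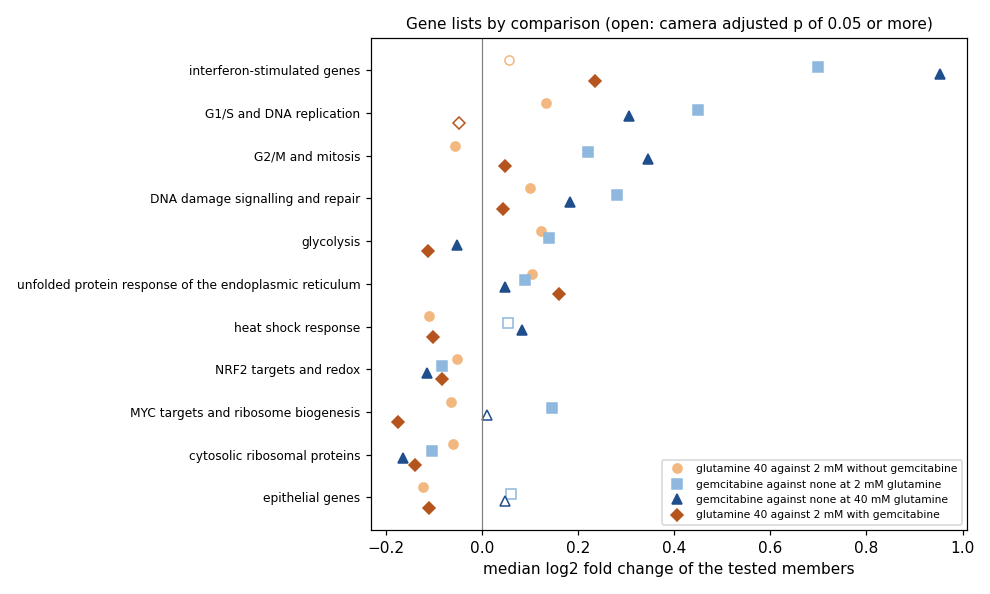
Median log2 fold change of the tested members of 11 gene lists (x axis) in the 4 pairwise comparisons (symbols); open symbols did not pass camera with the preset correlation. The median of the interferon-stimulated genes was 0.699 and 0.953 with the drug and 0.057 and 0.235 with glutamine.

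Between drug-treated cells, 40 mM glutamine lowered genes of ribosome biogenesis and nucleotide synthesis and raised interferon-stimulated genes. By the rule of level and separation, DHRS2 fell by 0.81 ± 0.06, L1CAM by 0.61 ± 0.061 and KRT18 by 0.59 ± 0.035, followed by ANGPTL4, PTX3, UNC93B1, RIN1 and DKK1 at −0.55 to −0.48. The largest rises were the uncharacterised LOC101930276 (0.70 ± 0.066), TSPYL2 (0.61 ± 0.047), DDX60 (0.60 ± 0.082) and OAS3 (0.49 ± 0.064), with APOL6, SLC33A1, CBX5 and SORT1 at 0.43 to 0.47. The call of ANGPTL4 ended with robust moderation (adjusted p = 0.117), where its log2 fold change stayed at −0.55.

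Of 41 MYC target and ribosome biogenesis genes, 0 rose and 29 fell in drug-treated cells at 40 mM (0 and 30 adjusted over the list alone, camera adjusted p = 1.17e-18, and adjusted p = 0.0183 with an estimated correlation), among them NPM1 (−0.29 ± 0.026), FBL (−0.32 ± 0.034) and MYC itself (−0.28 ± 0.031). In the purine and pyrimidine synthesis list 0 of 24 rose and 13 fell (0 and 14 adjusted over the list alone, camera adjusted p = 7.38e-06, and adjusted p = 0.0493 with an estimated correlation), such as IMPDH2 (−0.33 ± 0.03). Of 38 interferon-stimulated genes, 21 rose and 3 fell (22 and 3 adjusted over the list alone, camera adjusted p = 3.56e-09, and adjusted p = 0.0365 with an estimated correlation), with IFIT1 at 0.41 ± 0.042. Unfolded protein response genes had 12 rises and 1 fall among 23 (13 and 2 adjusted over the list alone, camera adjusted p = 6.38e-07, and adjusted p = 0.0423 with an estimated correlation). Of 14 epithelial genes, 0 rose and 6 fell (0 and 6 adjusted over the list alone, camera adjusted p = 0.000115, and adjusted p = 0.0332 with an estimated correlation), with KRT19 at −0.45 ± 0.035. SLC7A5 fell by 0.23 ± 0.032, SLC1A5 by 0.19 ± 0.032 and SLC29A1 by 0.32 ± 0.041. DCK had 0.27 ± 0.082, and its call ended without replicate 1 or 2 at 2 mM with drug (0.24 and 0.26, adjusted p = 0.0791 and 0.0543), without replicate 2 or 3 at 40 mM with drug (0.25 and 0.21, adjusted p = 0.0635 and 0.112) and after removal of the trend (0.22, adjusted p = 0.0655).

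Counts in drug-treated cells were 1102 genes higher and 1663 lower at 40 mM, or 21.6% of those tested (limma), so 39.9% of calls were higher. Quantile normalization gave 1245 higher and 1239 lower, or 50.1% higher. Of 77 ribosomal protein genes, 0 rose and 58 fell (2 and 65 adjusted over the list alone, camera adjusted p = 3.48e-21, but adjusted p = 0.179 with an estimated correlation and 0.0879 after removal of the trend with level, GC content and length). Of 13 mitochondrially encoded genes, 0 rose and 8 fell (0 and 10 adjusted over the list alone, list median −0.202, camera adjusted p = 1.62e-05, but adjusted p = 0.266 with an estimated correlation, and −0.028 with 0.146 under quantile normalization). These genes took 4.2982% and 4.148% of reads with the drug at 2 and 40 mM. Single libraries ran from 4.1571% to 4.3891% and from 3.8328% to 4.3662%, so the shares overlap. Quantile normalization sets values by rank and can by itself shrink differences of such abundant genes. That was not tested, so its value decides little here. Of 75 nuclear-encoded respiratory chain genes, 0 rose and 25 fell (0 and 29 adjusted over the list alone, list median −0.089, camera adjusted p = 1.05e-06, but adjusted p = 0.358 with an estimated correlation). The 3 libraries at 40 mM with drug stand apart from the other 9 in the reads of long non-coding RNAs (0.6775% to 0.6857% against at most 0.6618%) and of untested genes (0.1081% to 0.1102% against at most 0.0969%). The log2 fold changes in this comparison also ran with the level of the gene, its GC content and its transcript length. Spearman rho across genes was −0.23, −0.21 and 0.11, though genes are not independent replicates.

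The interaction asks whether the drug response differed between glutamine levels. Genes of DNA replication rose less with the drug at 40 mM, and interactions of the glycolysis list were negative. CDC6 rose by 0.90 ± 0.048 at 2 mM and 0.44 ± 0.048 at 40 mM (interaction −0.46 ± 0.067, limma adjusted p = 0.000119), and PDK1, which restrains pyruvate oxidation, rose by 0.51 ± 0.06 at 2 mM and had −0.06 ± 0.06 at 40 mM (interaction −0.57 ± 0.085). PKM had 0.02 ± 0.026 at 2 mM and fell by 0.25 ± 0.026 at 40 mM (interaction −0.27 ± 0.036). Negative interactions were also found for MCM5 (−0.38), PCNA (−0.34), MCM4 (−0.27), LDHA (−0.27), SLC2A1 (−0.40) and the splicing factor gene SRSF6 (−0.40). The phosphate transporter SLC20A1 (0.43 ± 0.045), the interferon-stimulated IFIT1 (0.41 ± 0.06) and EIF4A2 (0.27 ± 0.039) had positive ones.

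Of 60 replication genes, 0 had a positive and 21 a negative interaction (0 and 34 adjusted over the list alone, list median −0.178, camera adjusted p = 3.69e-24, and adjusted p = 0.0283 with an estimated correlation). For glycolysis the counts were 0 and 13 of 25 (0 and 20 adjusted over the list alone, list median −0.219, camera adjusted p = 3.91e-22, and adjusted p = 0.0487 with an estimated correlation). With the drug at 2 mM, 12 glycolysis genes rose and 2 fell (16 and 2 adjusted over the list alone, list median 0.139, camera adjusted p = 2.09e-05, but adjusted p = 0.306 with an estimated correlation). At 40 mM 2 rose and 9 fell (2 and 9 adjusted over the list alone, list median −0.051, camera adjusted p = 0.0272, but adjusted p = 0.576 with an estimated correlation). That last call also ended under quantile normalization (median −0.043, adjusted p = 0.419), after removal of the trend (−0.02, 0.584), and without replicate 1 at 40 mM (−0.024, 0.129) or replicate 2 at 40 mM with drug (−0.033, 0.135). Among 38 interferon-stimulated genes 4 were positive and 0 negative (7 and 0 adjusted over the list alone, list median 0.145, camera adjusted p = 3.43e-07, and adjusted p = 0.0435 with an estimated correlation). MYC targets and ribosome biogenesis had 0 positive and 5 negative of 41 (0 and 14 adjusted over the list alone, camera adjusted p = 1.18e-09, and adjusted p = 0.0423 with an estimated correlation). Of 56 mitosis genes, 11 were positive and 0 negative (22 and 0 adjusted over the list alone, camera adjusted p = 8.77e-16, but adjusted p = 0.0608 with an estimated correlation).

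In all, 93 genes had a positive and 188 a negative interaction, 2.2% of those tested (limma). Positive ones were 33.1% of calls. Quantile normalization gave 116 and 96, or 54.7% positive. Without replicate 1 at 2 mM the counts were 49 and 116, without replicates 1, 2 and 3 at 2 mM with drug 51 and 104, 47 and 110, and 53 and 127, without replicate 3 at 40 mM 57 and 108, and without replicates 1 and 2 at 40 mM with drug 52 and 122, and 60 and 129.

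**Figure D3:**
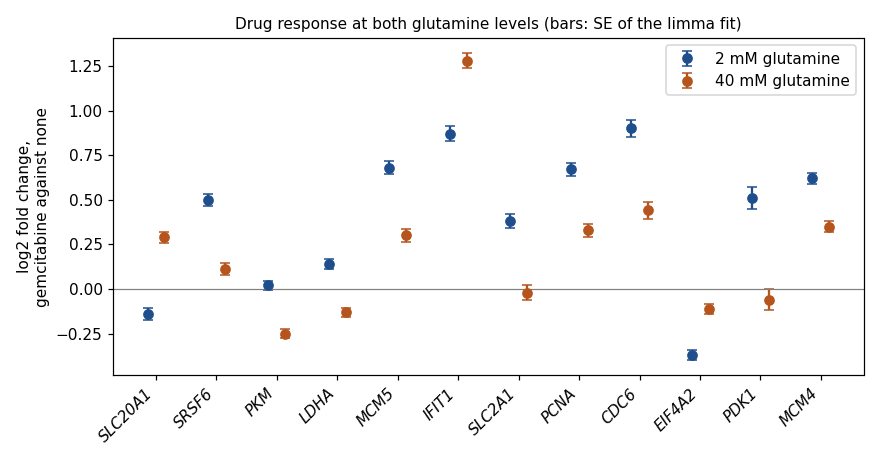
Log2 fold change of gemcitabine against none (y axis) at 2 and 40 mM glutamine for the 12 genes with the smallest adjusted p of the interaction; bars are the SE of the limma fit. CDC6 lies at 0.90 and 0.44, and SLC20A1 at −0.14 and 0.29.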

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

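The results listed here are differences in the drug response between glutamine levels, tested by the planned interaction, and reads in genes that no comparison used; tests of them, and split counts for all comparisons, follow. The tests of library scaling, of trends, of a ceiling, of depth, of GC content and length, and of unspliced and nuclear RNA, and the counts of other splits and of permuted residuals, were chosen after the results were seen.

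A total of 93 genes had a positive and 188 a negative interaction. Of 100 random splits of the 12 libraries into 4 groups of 3, the real one included, 5 gave as many genes, so this count by itself does not exclude chance; the real split gave 281 genes and the highest other split 4681. Most of the 4 other splits point to a structure of the samples, since they measure the drug or glutamine effect and not an interaction. In 1 the interaction contrast set all drug-treated against all untreated libraries (alignment 1), and in 2 it set the glutamine levels against each other (978 and 1989 genes). The last was aligned in part (0.67 with the drug and 0.33 with glutamine, 748 genes). Other splits with the same alignments gave 0 genes, so alignment alone does not explain its count. All remaining splits gave 6 genes or fewer. With the drug and glutamine effects kept, the residuals of the additive fit were permuted over the libraries. Of 100 orders, 1, the real one, gave 281 genes and the highest other 45, which argues against chance for the count. A share of 1 in 100 is the smallest that these orders can give. They cannot test a technical shift shared by the 3 libraries of a group. For the pairwise comparisons, 10 splits of 6 libraries are too few for a share under 0.05. The real splits gave 2242, 4422, 3879 and 2765 genes, as many as in 1 split each, and the highest other splits gave 0, 0, 0 and 1.

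Of 304 named genes, 59 were singled out by the interaction. Among cell cycle and DNA genes the interaction was −0.46 for CDC6, −0.38 for MCM5 and CHAF1A, −0.34 for PCNA, −0.33 for TK1, −0.32 for UHRF1, −0.27 for MCM4 and RRM2, −0.26 for CHAF1B, −0.24 for DTL, −0.23 for MSH6 and −0.43 for FAM111B. It was 0.21 for BUB1, 0.24 for CKS2, 0.25 for HMGB2 and 0.29 for HMMR. Among glycolysis and hypoxia genes it was −0.83 for PFKFB4, −0.57 for PDK1, −0.40 for SLC2A1, −0.28 for GAPDH, −0.27 for PKM and LDHA, −0.26 for KDM4B, −0.25 for EGLN1, −0.23 for ERO1A, −0.22 for PFKP, −0.21 for ENO1 and −0.19 for TPI1. Interferon-linked genes had 0.46 (DDX60), 0.41 (IFIT1) and 0.32 (IFITM1). For IFITM1 this was a smaller fall and not a larger rise, with −0.39 ± 0.046 at 2 mM and −0.08 ± 0.046 at 40 mM.

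Surface, matrix and cytoskeletal genes had interactions of 0.40 (CLDN4), 0.34 (CCN1), 0.17 (ITGB4) and −0.14 (KRT8). Transporters had 0.43 (SLC20A1), 0.32 (SLC33A1) and −0.26 (SLC29A1). Metabolic genes had −0.32 (DHCR7), −0.24 (CTPS1), −0.22 (GPT2), 0.21 (PCK2) and 0.24 (TXNIP). Mitochondrial genes had −0.29 (ND3), −0.21 (ATP6) and −0.17 (ATP5PB). Others were SDF2L1 (−0.42), SRSF6 (−0.40), VGF (−0.35), DKK1 (−0.34), MYC (−0.18), NOP56 (−0.18), SGK1 (−0.18), EIF4A2 (0.27), KLHL24 (0.32) and LOC101930276 (0.44).

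Of these 59 genes, 57 were called in the same direction with median-of-ratios scaling, without ATP5PB (−0.16, limma adjusted p = 0.0597) and SGK1 (−0.17, 0.0653), and 45 with quantile normalization. Quantile normalization left GAPDH at −0.04, ENO1 at −0.07, KRT8 at −0.06, ATP6 at −0.10, SGK1 at −0.12, NOP56 at −0.14, MYC and ATP5PB at −0.15 each, ERO1A at −0.17, GPT2 at −0.19, DTL at −0.21, EGLN1 at −0.22, KDM4B at −0.24 and ND3 at −0.25, with limma adjusted p from 0.0503 to 0.688. Setting values by rank, as quantile normalization does, can by itself shrink differences of the most abundant genes, which was not tested. PKM went from −0.27 to −0.32 under it, and LDHA stayed at −0.27. Whether the values of GAPDH and ENO1 were shrunk in this way therefore stays open. After removal of the trend, 0 of the genes with annotation changed direction, with GAPDH at −0.21, ENO1 at −0.15 and TPI1 at −0.13.

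By list, 16 of 32 lists passed camera in the interaction, and 4 of them with an estimated correlation: G1/S and DNA replication, glycolysis, interferon-stimulated genes, and MYC targets and ribosome biogenesis. Hypoxia did not (adjusted p = 0.236). The list medians were −0.18 for G1/S and DNA replication, −0.22 for glycolysis, −0.21 for hypoxia, 0.11 for mitosis, 0.14 for interferon-stimulated genes and −0.11 for MYC targets and ribosome biogenesis. Others were −0.07 for ribosomal proteins, −0.10 for mitochondrially encoded genes, −0.04 for the nuclear-encoded respiratory chain, −0.07 for nucleoside transport and gemcitabine metabolism, −0.03 for purine and pyrimidine synthesis and −0.06 for DNA damage genes. The remaining medians were 0.06 for ATF4 genes, 0.07 for MAPK and immediate-early genes, 0.05 for mesenchymal genes and 0.08 for senescence-linked genes.

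With the drug, replication genes rose less at 40 mM than at 2 mM, and glycolysis genes went from a list median of 0.139 to −0.051. Under quantile scaling, the nearer to 0 of 2 other scalings, the interaction medians were −0.163 and −0.184. After removal of the trend with level, GC content and length they were −0.157 and −0.177. Each lay under −0.10 by more than its bootstrap SE, which argues against scaling or the trend as the whole cause. The bootstraps here and below resampled genes as if they were independent. Their SEs may therefore run low and do not measure variation between cultures. At 40 mM the drug still raised 53 of 60 replication genes and lowered 0 (list median 0.306), which argues against a ceiling already reached there with glutamine alone. A ceiling common to both glutamine levels, approached in part with glutamine alone, needs lists no lower at 40 mM in drug-treated cells. There the medians were −0.048 ± 0.016 and −0.111 ± 0.025 (bootstrap SE), with 40 of 60 and 22 of 25 members negative. These values, and −0.042 ± 0.016 and −0.106 ± 0.025 under median-of-ratios scaling, argue against such a common ceiling. It stays open for both lists, because quantile scaling left −0.006 ± 0.018 and −0.037 ± 0.024 and removal of the trend −0.018 ± 0.016 and −0.036 ± 0.027, all within 2 SEs of 0. A changed response of the cells to the combined treatment may be an explanation and was not tested apart from a common ceiling.

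The larger response of interferon-stimulated genes at 40 mM had a list median of 0.145, with 30 of 38 members positive and 8 negative. It includes smaller falls as well as larger rises: 4 members fell with the drug at 2 mM and 1 at 40 mM. The list median was 0.152 ± 0.044 under median-of-ratios scaling, 0.133 ± 0.044 under quantile scaling and 0.132 ± 0.039 after removal of the trend (bootstrap SE). Each value stayed positive by more than its SE, which argues against scaling or the trend as the whole cause for this list. The quantile and trend values do not lie clear of the bound of 0.10. Scaling or the trend may therefore account for part of this difference. That part cannot be told from a biological cause, because the spread between the 38 members is too wide.

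Genes under the level needed for testing took 0.1091% of reads in the 40 mM libraries with drug, against 0.0930% to 0.0939% in the other groups. These 3 libraries also have the highest scaling factors, 1.0263 to 1.0292 against at most 1.002, though a share of reads does not depend on them. With all libraries thinned to equal reads, the lowest of the 3 shares was 0.108%, against at most 0.0967% in the other 9. Random thinning leaves the expected share unchanged, so that comparison cannot test depth. The 3 libraries held 23488621 to 24612122 reads, inside the range of the other 9 (21723094 to 32811746). At similar depth, replicates 1 and 2 at 40 mM without drug (23672563 and 23967249 reads) had lower shares, 0.0926% and 0.0903%. These values argue against depth as the cause. As causes of this excess of reads, GC content and length are argued against where annotated. Removing their trend left 1.05 ± 0.033 of the difference between tested genes of low and high level (78.8% of the low ones). For 1489 of the 2301 untested genes the trend predicted −0.04 ± 0.008 of the rise (bootstrap SE). The fold changes in drug-treated cells still ran with GC content across tested genes (Spearman rho −0.21). Nuclear or unspliced RNA may contribute and stays open: long non-coding RNAs took 0.6775% to 0.6857% of reads in these libraries against at most 0.6618% in the other 9, small nucleolar RNAs 0.0099% to 0.0102% against at most 0.0097%, and at equal level, GC content and length long non-coding RNAs lay 0.028 ± 0.010 above protein-coding genes, while the partial Spearman correlation with gene span, −0.036, decides nothing if introns were not counted.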

How the results depend on the processing

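Voom, the test against a fold of 1.1 and the removal of trends were chosen after the data were seen; the other settings were chosen before the data were examined. The planned DESeq2 and edgeR fits were not run, by a choice that rested on the deposited log scale, although whole reads were recovered. The fit with only the compared groups gives no interaction, and neither it nor the test against a fold of 1.1 was run for lists. Of 555 results for named genes, 334 kept direction and side of the threshold in all 26 settings that apply to them, as did 26 of 83 list results. Counts of the 4 pairwise comparisons stayed within 1.5 times under all settings except the test against a fold of 1.1. Without single libraries, the interaction gave 47 to 103 positive and 104 to 263 negative genes. Positive calls were 49 without replicate 1 at 2 mM, 51, 47 and 53 without replicates 1, 2 and 3 at 2 mM with drug, 57 without replicate 3 at 40 mM, and 52 and 60 without replicates 1 and 2 at 40 mM with drug. Negative calls without those libraries were 116, 104, 110, 127, 108, 122 and 129. Negative interaction calls numbered 96 under quantile normalization and also 96 after removal of the trend. Against a fold of 1.1, higher and lower genes numbered 74 and 142 for glutamine alone, 696 and 501 for the drug at 2 mM, 638 and 428 for the drug at 40 mM, 81 and 161 for glutamine with drug, and 2 and 7 for the interaction, since that test asks for a larger change. In drug-treated cells VIM, at −0.10, had 0.138 under quantile normalization and 0.006 after removal of the trend, where FASN, also at −0.10, had 0.017; the cause was not tested.

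Libraries with the same replicate number showed no clear shared deviation. Correlations over 18 such pairs ran from −0.077 to 0.048, within the −0.08 to 0.092 of the other pairs. Still, 7 of 12 libraries correlated best with their own number, more than an even spread over the numbers would give. The check therefore does not settle whether equal numbers were paired. A replicate block gave 95 positive and 211 negative interaction genes, 1102 and 1190 for glutamine alone, and changed 1 named gene (TXNIP in drug-treated cells, −0.108, adjusted p = 0.0341) and 1 list (DNA damage genes in the interaction, adjusted p = 0.0502). Quantile normalization ended 16 list calls, removal of the trend 13 and an estimated correlation 57, and 16 did not pass fry, which asks whether a list changed at all and not whether it differs from other genes. How depth affects calls by level was not tested. Voom on the recovered reads called 1051 and 1150 genes for glutamine alone and 93 and 205 for the interaction.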

Other observations

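Replication-dependent histone genes and genes of the hyperosmotic response were not described above. The histone genes took little of the reads, with group means from 0.0029% to 0.0045%. Only 11 of 30 reached the level needed for testing, so these may not stand for the class. H2BC12, a replication-dependent histone gene, rose with 40 mM glutamine in drug-treated cells (log2 fold change 1.07 ± 0.123, SE, n = 3 per group) and without the drug, where it was 2.3-fold higher (limma adjusted p = 7.68e-09), although the histone list, with 3 rises and 1 fall among 11 tested genes without the drug, did not pass camera there (adjusted p = 0.124). In drug-treated cells 3 histone genes rose and 0 fell (3 and 0 adjusted over the list alone, list median 0.203, camera adjusted p = 0.0142, but adjusted p = 0.0856 with an estimated correlation and 0.0688 under quantile normalization). Of 17 hyperosmotic response genes, 5 rose and 1 fell with glutamine alone (6 and 1 adjusted over the list alone, camera adjusted p = 0.0155, but adjusted p = 0.101 with an estimated correlation). SLC5A3, a transporter of the osmolyte inositol, rose by 0.25 ± 0.048 with glutamine and fell by 0.44 ± 0.048 with the drug at 2 mM. AKR1B1, which makes sorbitol, rose by 1.36 ± 0.104 and 1.42 ± 0.104 with the drug at 2 and 40 mM and had 0.26 ± 0.104 with glutamine alone, where it did not pass.

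Values of CD68 at 40 mM, CD8A, the levels of COL1A2, H2BC12 without the drug, and SLC5A3 and AKR1B1 outside the comparisons for which the rule names them, were chosen after they were seen. Few markers of other cell types reached the level needed for testing: 3 of 15 leukocyte genes, 3 of 15 fibroblast and endothelium genes and 4 of 20 pancreatic acinar, endocrine and ductal genes. Not all of these were low. COL1A2, on the fibroblast list and also on the mesenchymal list, averaged 757 RPM without and 606 RPM with the drug at 2 mM. At 40 mM it averaged 885 and 678 RPM. Of the leukocyte genes, CD68 rose by 1.09 ± 0.062 and 1.01 ± 0.062 with the drug at 2 and 40 mM, while CD8A had 0.34 ± 0.158 and −0.02 ± 0.158 and did not pass. Glutamine responses without and with the drug, which share no libraries, had 393 higher and 657 lower genes in common, where independent lists would share 92.7 and 151.6; 29 of 1079 genes called in both went in opposite directions.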
